A study of Homo sapiens with 6 samples.

How the data were processed

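RNA sequencing libraries of cells labelled as CD133-selected HepG2 were compared between 3 control and 3 LAPTM4B knockdown libraries, which the sample titles assign to their groups. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA preparation kit. The genome build was hg38, per the submitters' processing notes. The aligner, the counting program, the annotation release and the use of strand are not given in the sources used here, so reads from a gene and an overlapping partner may have been counted together; 48 of the 175 named genes overlap another gene at 1 CPM or more.

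The deposited table held, for each of 61806 genes and each library, a raw whole-number count and an FPKM value, per the file headers. It also gave the exonic length of each gene in bases, as the authors' deposited size column (a quantity other than an expression unit), with coordinates and annotation terms. Recomputing FPKM as the count divided by that length and by the total count of the library gave 100% of the deposited FPKM values within 0.0051. No count was in any library for 27305 genes. Symbols were taken from a reference table of gene names, which matched 61757 of the gene identifiers. Of the identifiers also in GENCODE release 29, 99.98% overlapped that annotation's gene on the same chromosome.

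The choices of test, gene lists, alternatives and naming rule were made before the data were examined. The design assumed that the table would hold FPKM and named a count test as the main one if counts were present, which was the case. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment over the 16354 genes tested and a threshold of 0.05. The filter removed 18147 genes with counts, and the genes kept held 99.8% of all counts. TMM factors lay between 0.970 and 1.03, and the common biological coefficient of variation was 4.16%. The SE of a log2 change was taken as its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 28 of 31 lists with at least 5 tested members; camera with an estimated correlation and fry were run beside it. All 613 list members were matched to the table. Annotation terms with 15 to 300 tested genes were tested likewise, and of terms sharing over 50% of their genes 1 is described.

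Named genes were LAPTM4B; the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05, a proper symbol, a mean of at least 5 FPKM in the higher group and no overlap between the groups; up to 4 members of each list with the smallest p; a fixed set of genes of interest; and up to 3 members of each annotation term described. The table gives no biotype, so pseudogenes could enter. Genes outside this rule are said to be named after their values were seen. Of the genes picked by the rule, 6 are not reported here.

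Replicates were compared before averaging. No columns were identical, and within each group every pair differed by more than sampling noise (chi-square per gene 1.89 to 4.38 over genes with at least 20 counts). On log2 CPM the lowest correlation within a group was 0.990 and the highest between groups 0.958, both across genes, which are not independent replicates. The first principal component held 76.5% of the variance and separated the groups. The labels name no batch, day or culture, so no relation could be recomputed within batches.

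Alternatives were DESeq2 1.42.0, edgeR with median-of-ratios factors, without a count filter, with the replicate number as a block and without each library in turn. Limma was run on log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM, with pseudocounts of 1 and 0.01, without a filter and with a mean of at least 5, rescaled to TPM, with median-of-ratios or trimmed-mean factors, with quantile normalisation, without a trend, with robust estimation and with array weights. An edgeR fit with each library's trend on GC content and length removed, using GENCODE release 29 transcripts, and 5 further gene lists (targets of NRF2, LXR and HIF, EGFR ligands and trophoblast genes) were added after seeing the data. On counts simulated for 16354 genes from the real means and library sizes, edgeR recovered 58%, 78%, 86% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold (50 genes each) with 9 false calls. The simulated changes went up and down in equal number and all other genes were unchanged. In the real data 55.9% of the genes tested were called, so these rates may not hold there. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.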

Results

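Expression was measured by RNA sequencing in cells labelled as HepG2, an established human hepatoma line, and as selected for CD133, the surface glycoprotein encoded by PROM1 that is used to isolate stem-like tumour cells. The 6 libraries fall into 2 groups of 3: control cells, and cells in which LAPTM4B, a membrane protein of late endosomes and lysosomes, was knocked down. The series title places the comparison within a question about LAPTM4B, the transcriptional co-activator YAP and stem-like properties of hepatocellular carcinoma. Gene counts summed to 18378383, 15667396 and 19987318 in control replicates 1 to 3 and to 15446933, 15204269 and 16303949 in knockdown replicates 1 to 3. A limit of 3 counts corresponded to 0.150 to 0.197 CPM, the unit in which counts are scaled to a common library total, and covers counting error only. Levels are given as TMM-normalised CPM, mean ± SD of 3 libraries, and changes as knockdown relative to control, with the standard error (SE) of the log2 change. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

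LAPTM4B itself was lower in the knockdown. The gene (chromosome 8, 97775057 to 97853013, hg38) was at 334 ± 13.9 CPM in control cells and at 232 ± 5.05 CPM after knockdown. This was a log2 change of -0.53 (SE 0.04; edgeR adjusted p = 3.25e-12), and the level fell by 30.6%. The control libraries were at 327, 325 and 350 CPM and the knockdown libraries at 227, 237 and 232 CPM, so the groups did not overlap. Its family member LAPTM4A rose from 108 ± 5.15 to 148 ± 6.21 CPM (edgeR adjusted p = 1.83e-09). LAPTM5, a haematopoietic member, fell from 2.80 ± 0.346 to 0.729 ± 0.101 CPM (edgeR adjusted p = 7.76e-06).

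**Figure D1:**
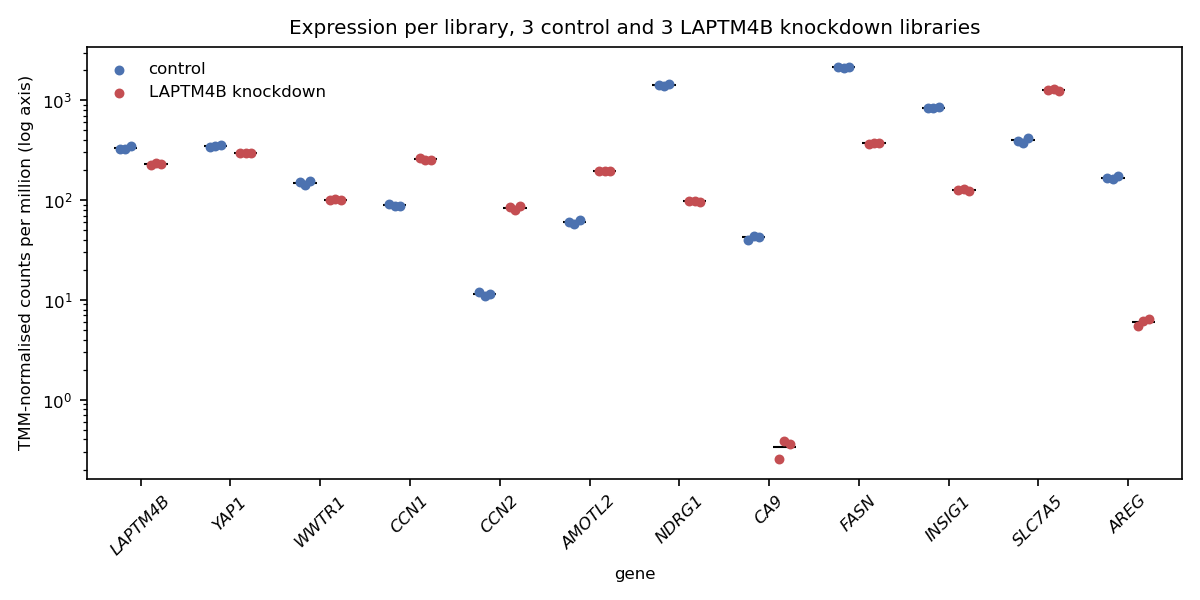
TMM-normalised CPM (log axis) of 12 genes in each of the 3 control (blue) and 3 LAPTM4B knockdown (red) libraries; points are libraries and black lines group means. LAPTM4B lies between 227 and 237 in the knockdown libraries and between 325 and 350 in the control libraries, and the shifts of CA9, NDRG1 and AREG are far larger than that of LAPTM4B.

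Of 16354 genes tested, 4584 were higher and 4559 lower in the knockdown at an adjusted p under 0.05 (edgeR), which is 55.9% of the genes tested. A change of at least 2-fold was reached by 638 of the higher and 1213 of the lower genes. The most increased genes included CPA4, a carboxypeptidase (chromosome 7, 130293134 to 130324180), which went from 2.05 ± 0.574 to 56.3 ± 1.21 CPM, and ALPP, placental alkaline phosphatase (chromosome 2, 232378724 to 232382889), from 14.8 ± 1.65 to 341 ± 14.7 CPM. EDN1, the precursor of the vasoconstrictor endothelin, rose 9.60-fold, the stress-response regulator NUPR1 9.48-fold, and the aldo-keto reductase AKR1C2 9.46-fold. The matricellular protein genes CCN2 and CCN5 rose 7.30-fold and 5.99-fold, the keratin genes KRT7 and KRT80 6.45-fold and 5.95-fold, TRIM16L 6.31-fold and the secreted ligand WNT5A 5.79-fold. The ribosomal protein pseudogene RPL12P14 was also among the 12 largest increases, from 0.496 ± 0.213 to 8.75 ± 0.740 CPM.

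Losses were deeper than gains. STC1, a secreted glycoprotein hormone (chromosome 8, 23841929 to 23854806), went from 420 ± 18.4 CPM to 1.20 ± 0.266 CPM, a log2 change of -8.45 (SE 0.08; edgeR adjusted p = 4.17e-31). TSPAN19, a tetraspanin gene, went from 172 ± 3.14 to 1.38 ± 0.273 CPM, and CA9, carbonic anhydrase IX, from 42.3 ± 1.90 to 0.334 ± 0.0700 CPM. The EGF receptor ligand AREG fell 27.9-fold, the hyaluronan-binding protein gene CEMIP 29.1-fold, the bHLH-PAS factor gene ARNT2 26.8-fold, the cholesterol exporter ABCA1 22.0-fold and the adhesion molecule CEACAM1 18.03-fold. The cytokine gene IL33 fell from 28.97 ± 1.33 to 0.330 ± 0.143 CPM and the serpins SERPINB3 and SERPINB4 from 22.97 ± 1.52 and 26.03 ± 1.62 CPM to 0.351 ± 0.163 and 0.416 ± 0.195 CPM. S100A9, a calcium-binding protein gene, fell from 6.06 ± 1.38 to 0.270 ± 0.179 CPM. In the knockdown these last genes rested on few reads, with 3 to 8 counts per library for IL33 and 1 to 6 for S100A9. The same holds for CA9, with 4 to 6 counts per knockdown library. SERPINB3 with SERPINB4, ALPP with its close relatives, AKR1C2 with AKR1C1, TRIM16L with TRIM16, and RPL12P14 with its parent gene are near-copies among which the counting could have split reads, so their individual values are uncertain. Of these 24 genes, 7 also overlap another expressed gene, among them KRT7, CA9, CEMIP and CEACAM1.

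Known targets of YAP and TAZ were mostly higher in the knockdown: of 22 tested, 17 rose, 2 fell and 3 did not pass, with a median log2 change of 0.40. CCN2 (chromosome 6, 131948176 to 131951372) rose from 11.5 ± 0.567 to 84.1 ± 3.54 CPM and CCN1 (chromosome 1, 85580761 to 85584589) from 89.3 ± 2.70 to 256 ± 7.29 CPM. AMOTL2, an angiomotin family gene, rose 3.26-fold, and ANKRD1 from 1.42 ± 0.644 to 4.36 ± 1.12 CPM. The 2 members that fell were NT5E, the ecto-enzyme CD73, from 636 ± 10.7 to 85.5 ± 4.81 CPM, and IGFBP3, an insulin-like growth factor binding protein gene named after its values were seen, from 156 ± 7.34 to 54.9 ± 2.53 CPM. The list was higher than other genes by camera (adjusted p = 1.03e-04), and adjusted p = 0.0588 with an estimated correlation. Adjusted over the list alone, 17 members were higher and 3 lower.

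The co-activator genes themselves were lower. YAP1 (chromosome 11, 102110447 to 102233424) fell from 350 ± 8.09 to 297 ± 2.53 CPM (log2 change -0.24, SE 0.03; edgeR adjusted p = 1.39e-06), and WWTR1, which encodes TAZ, from 149 ± 6.82 to 101 ± 1.45 CPM. Among 23 tested components of the Hippo pathway, 9 rose, 10 fell and 4 did not pass, and the list as a whole did not differ from other genes (camera adjusted p = 0.829; median log2 change 0.01, mean -0.03, test lower). Its TEAD1 gene, a DNA-binding partner of YAP, rose from 378 ± 13.8 to 527 ± 6.89 CPM. NF2, an upstream activator of the pathway, rose 1.61-fold and AMOTL1 fell 1.86-fold. TEAD4 was at 38.8 ± 1.29 and 43.1 ± 1.13 CPM (edgeR adjusted p = 0.0350), a call lost with DESeq2 (adjusted p = 0.105) and with edgeR without a count filter (0.0779). The TEAD4 call was also lost with edgeR without control replicate 1 (0.177) or 2 (0.0833) and without knockdown replicate 1 (0.0657) or 3 (0.114).

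**Figure D2:**
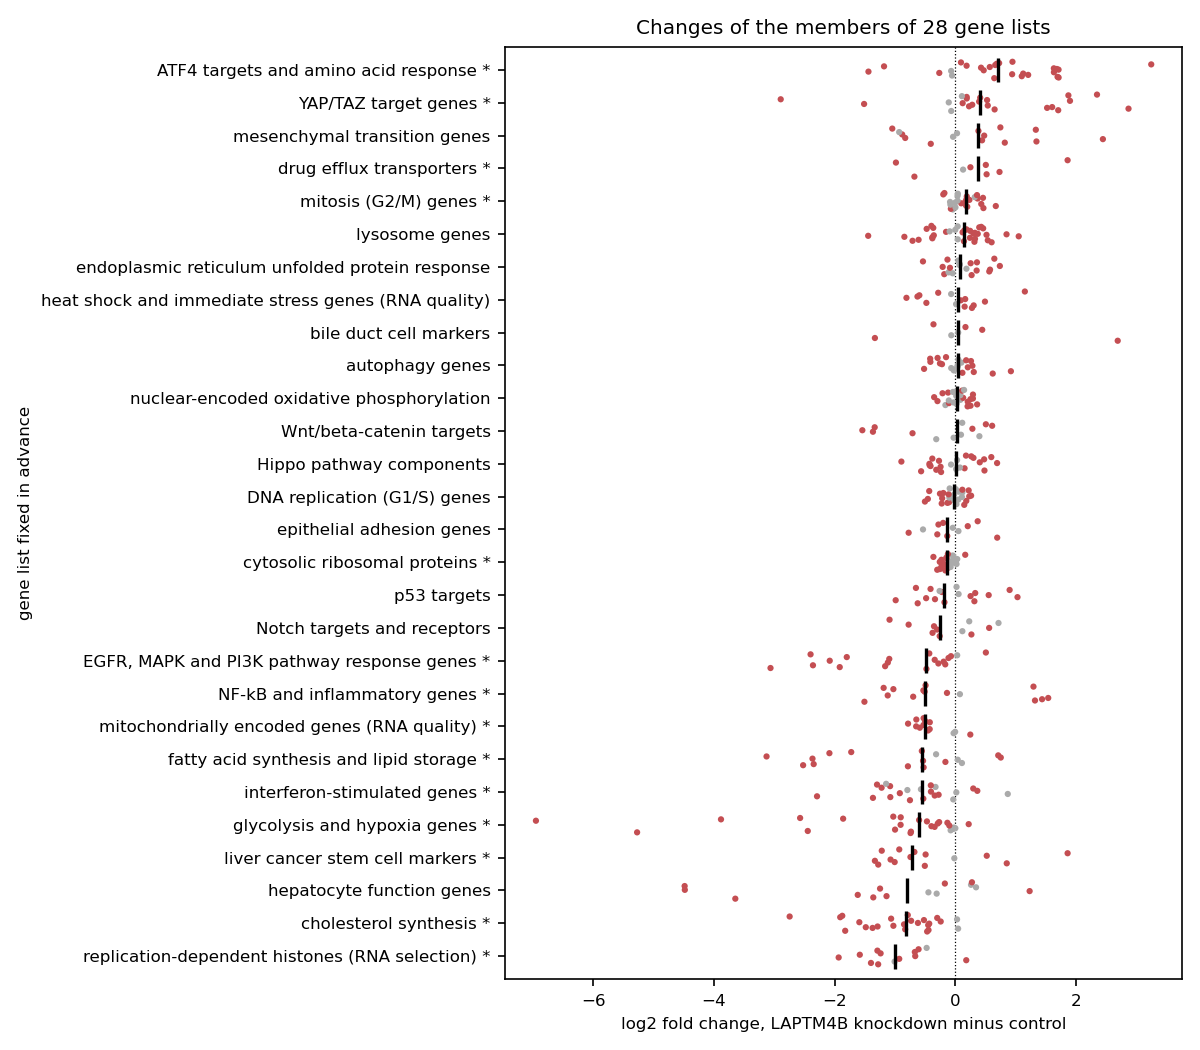
Log2 fold change (knockdown minus control) of each tested member of 28 gene lists fixed before the data were examined; red points pass an adjusted p of 0.05 (edgeR), grey points do not, black bars are list medians, and an asterisk marks lists passing camera with a preset correlation. The median lies at 0.70 for ATF4 targets, 0.40 for YAP/TAZ targets and -0.81 for cholesterol synthesis; the ribosomal call is lost under TPM scaling and quantile normalisation, and the mitochondrial one under quantile normalisation.

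Of 24 markers used for liver cancer stem cells, 14 were expressed highly enough to test: 3 rose, 10 fell and 1 did not pass, with a median log2 change of -0.71. ANPEP, the surface peptidase CD13, fell from 366 ± 14.5 to 182 ± 10.7 CPM, CD47 from 162 ± 3.01 to 85.1 ± 4.46 CPM, CD44 from 1452 ± 38.2 to 1022 ± 14.5 CPM and MYC from 490 ± 22.7 to 293 ± 10.8 CPM. EPCAM and POU5F1 fell 2.43-fold and 2.11-fold from low levels. The 3 that rose were the drug efflux transporter ABCG2, from 10.7 ± 1.81 to 39.3 ± 2.28 CPM, and CD24 and BMI1, both named after their values were seen. KLF4 was at 86.8 ± 4.44 and 85.8 ± 4.67 CPM (edgeR adjusted p = 0.785). The list was lower by camera (adjusted p = 0.00527), and adjusted p = 0.296 with an estimated correlation. PROM1, the gene of the selection marker, was too low to test, with 1 to 3 counts per control library and 6 to 12 per knockdown library, so its transcript gives no sign of the labelled selection. SOX2 had 1 to 8 counts in any library, NANOG 0 to 2 and AFP, alpha-fetoprotein, 0 to 4.

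Many hepatocyte genes were scarcely detected in either group. Of 36, 9 had no count in any of the 6 libraries and 15 had at most 3 counts in every library. ALB, APOA1 and APOB, which encode albumin and the main apolipoproteins, were at 0 counts in all 6 libraries, where the limit of 3 counts was 0.197 CPM in the shallowest. Of the 14 genes that could be tested, 2 rose, 8 fell and 4 did not pass, and the list as a whole did not pass (camera adjusted p = 0.157). The urea cycle gene ASS1 rose from 586 ± 24.4 to 708 ± 5.39 CPM and the pioneer factor gene FOXA1 2.35-fold from 4.07 ± 0.517 CPM. FGB, a fibrinogen chain, fell from 12.1 ± 0.711 to 5.45 ± 0.106 CPM, and SERPINA1, alpha-1-antitrypsin, from 2.46 ± 0.686 to 0.185 ± 0.161 CPM. SERPINA1 had only 0 to 5 counts per knockdown library.

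**Figure D3:**
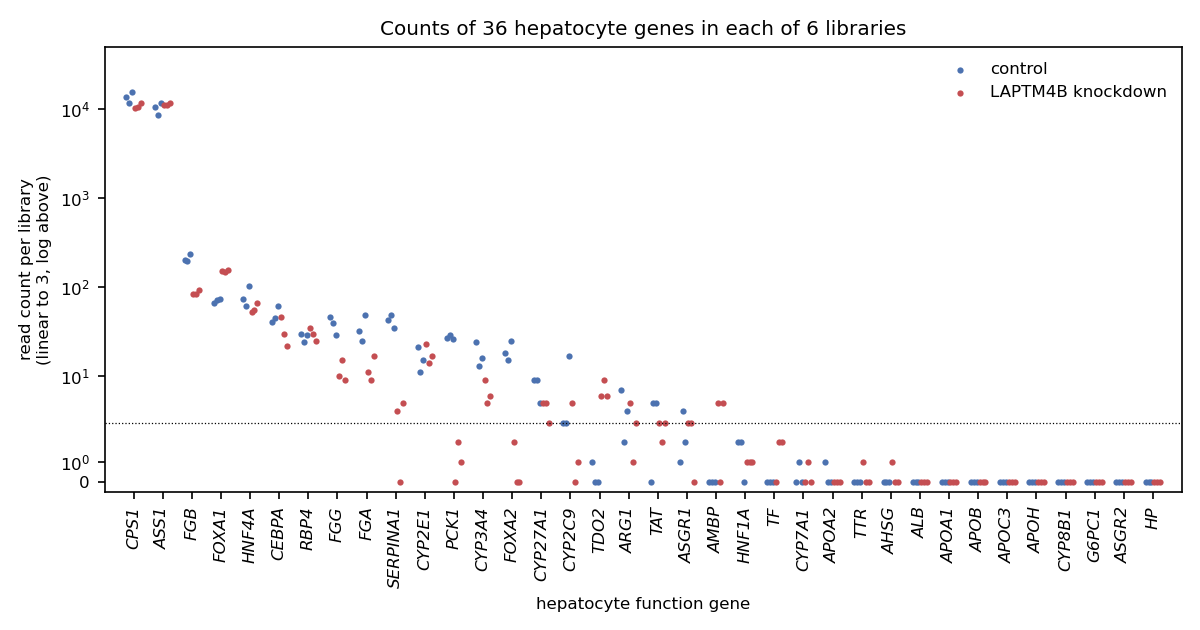
Read counts of 36 hepatocyte genes in each of the 3 control (blue) and 3 LAPTM4B knockdown (red) libraries, on an axis linear up to 3 counts and logarithmic above; the dotted line marks 3 counts. CPS1 and ASS1 are the most abundant, 15 genes stay at or under 3 counts in every library, and ALB, APOA1 and APOB are at 0 throughout.

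Markers of other cell types were mixed. Of the 10 bile duct markers 7 were tested, of which 3 rose, 2 fell and 2 did not pass (camera adjusted p = 0.518). KRT7 rose and SOX9, a progenitor-cell factor, fell from 32.8 ± 0.456 to 12.99 ± 1.23 CPM. Too few members of the fibroblast, endothelial and leukocyte lists were expressed for a list test. Of 4 fibroblast markers tested 2 rose, PDGFRB from 0.275 ± 0.127 to 3.13 ± 0.272 CPM and FAP from 0.263 ± 0.224 to 2.01 ± 0.333 CPM. COL1A1 did not pass (9.69 ± 1.75 and 11.7 ± 1.12 CPM; edgeR adjusted p = 0.0881), but did without control replicate 1 (0.0169). Both endothelial markers tested changed, ESAM upward from 51.9 ± 2.99 to 62.4 ± 3.19 CPM and PECAM1 downward from 1.88 ± 0.877 to 0.188 ± 0.00771 CPM. The knockdown level of PECAM1 was near the limit of 3 counts, so its small SD is no sign of precision. Of 2 leukocyte markers tested 1 fell, LAPTM5, and 1 did not pass.

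Genes of sterol and fatty acid synthesis fell together. In the cholesterol synthesis list 22 of 24 members fell and none rose, with a median log2 change of -0.81 (camera adjusted p = 2.3e-15; adjusted p = 0.0973 with an estimated correlation). INSIG1, the sterol-sensing regulator, fell from 845 ± 13.8 to 126 ± 2.20 CPM, a log2 change of -2.75 (SE 0.04; edgeR adjusted p = 3.32e-28). The synthase gene HMGCS1 fell 3.55-fold. Among 16 tested genes of fatty acid synthesis and lipid storage 11 fell, 2 rose and 3 did not pass, with a median of -0.55 (camera adjusted p = 1.53e-06; adjusted p = 0.0588 with an estimated correlation). Adjusted over the list alone, 12 of these were lower. Fatty acid synthase, FASN, fell from 2134 ± 39.05 to 371 ± 6.96 CPM, the desaturase SCD from 3446 ± 109 to 677 ± 10.97 CPM, the acetyl-CoA synthetase ACSS2 from 419 ± 0.911 to 47.9 ± 3.05 CPM and the regulator SREBF1 from 313 ± 14.6 to 60.6 ± 5.04 CPM.

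Glycolysis and hypoxia genes were lower as well: 20 of 25 fell, 1 rose and 4 did not pass, with a median log2 change of -0.60 (camera adjusted p = 1.55e-11; adjusted p = 0.115 with an estimated correlation). NDRG1, a hypoxia-induced gene (chromosome 8, 133237175 to 133302022), fell from 1433 ± 35.4 to 97.1 ± 1.598 CPM, hexokinase 2, HK2, from 404 ± 14.9 to 74.2 ± 1.61 CPM and the mitophagy receptor BNIP3 from 170 ± 4.82 to 46.8 ± 2.02 CPM. The member that rose, named after its values were seen, was the glycolytic enzyme PGAM1, with a log2 change of 0.22. Adjusted over the list alone, 21 members were lower.

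Targets of the amino acid response factor ATF4 were higher: 21 of 26 rose, 3 fell and 2 did not pass, with a median log2 change of 0.70 (camera adjusted p = 1.78e-08; adjusted p = 0.0588 with an estimated correlation). The amino acid transporter SLC7A5 rose from 397 ± 22.1 to 1272 ± 29.1 CPM and its partner subunit SLC3A2 from 141 ± 5.89 to 438 ± 6.24 CPM. DDIT4, an inhibitor of mTORC1 signalling that is also induced by hypoxia, fell from 454 ± 18.6 to 167 ± 7.15 CPM. Genes of the endoplasmic reticulum unfolded protein response did not pass as a list (8 higher, 5 lower and 6 not passing of 19; camera adjusted p = 0.129), but did in the higher direction with edgeR without a count filter (0.0174) or without control replicate 3 (0.0448), with limma on FPKM without a filter (0.00738) and with fry. DNAJB11 rose 1.48-fold, HERPUD1 1.49-fold and SEC61B 1.56-fold, and EDEM1 fell 1.45-fold. Adjusted over the list alone, 9 were higher.

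Lysosome genes moved in both directions, with 19 of 34 higher, 11 lower and 4 not passing (camera adjusted p = 0.177). The list passed in the higher direction only with limma on FPKM without a filter (0.0113) and with fry. NPC1, which exports cholesterol from lysosomes, fell from 464 ± 7.04 to 171 ± 4.71 CPM and the protease gene CTSB from 163 ± 5.67 to 99.6 ± 2.37 CPM. The membrane glycoprotein gene LAMP1 rose from 275 ± 13.4 to 418 ± 7.98 CPM. Autophagy genes were also split, with 8 of 22 higher, 7 lower and 7 not passing (camera adjusted p = 0.737). Adjusted over the list alone, 9 were higher. The cargo receptor SQSTM1 rose from 433 ± 7.81 to 665 ± 8.39 CPM and GABARAPL1 1.89-fold, whereas NBR1 fell 1.23-fold and PIK3C3 1.34-fold. Among 8 tested drug efflux transporters 5 rose, 2 fell and 1 did not pass (camera adjusted p = 0.0132; adjusted p = 0.147 with an estimated correlation). ABCC2 rose 1.66-fold, ABCC1 1.43-fold and ABCC5 1.42-fold, and 6 members were higher when adjusted over the list alone.

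Response genes of EGFR, MAPK and PI3K signalling fell: 17 of 19 were lower, 1 higher and 1 did not pass, with a median log2 change of -0.48 (camera adjusted p = 5.54e-09; adjusted p = 0.0588 with an estimated correlation). The phosphatase gene DUSP5 fell from 299 ± 5.57 to 35.7 ± 2.05 CPM, SPRY4, a feedback inhibitor of the pathway, 5.13-fold, PHLDA1 4.23-fold and IER3 3.48-fold. The member that rose was the cyclin gene CCND1, from 182 ± 8.20 to 259 ± 1.65 CPM. Interferon-stimulated genes were lower, with 13 of 22 down, 2 up and 7 not passing (median log2 change -0.55; camera adjusted p = 1.29e-04; adjusted p = 0.0588 with an estimated correlation). ISG15 fell 2.58-fold, OAS1 2.11-fold, OAS2 4.90-fold and IFIT1 1.69-fold, and 14 members were lower when adjusted over the list alone. Of 14 NF-kB and inflammatory genes 9 fell, 4 rose and 1 did not pass (camera adjusted p = 0.0274; adjusted p = 0.165 with an estimated correlation). The mitochondrial dismutase SOD2 fell 2.28-fold, BIRC3 2.04-fold, NFKB2 1.42-fold and the chemokine gene CXCL8 2.84-fold. All 4 members that rose did so by at least 2-fold, as did 4 of those that fell. The mean log2 change of this list was only -0.11, against a median of -0.50. Targets of Wnt/beta-catenin (3 higher, 4 lower, 5 not passing of 12; camera adjusted p = 0.829) and Notch genes (2 higher, 6 lower, 3 not passing of 11; camera adjusted p = 0.309) did not pass as lists. The Wnt list had a median of 0.03 but a mean of -0.28 and a test in the lower direction: GLUL fell 2.53-fold and NOTUM 2.91-fold, while TBX3 rose 1.53-fold. In the Notch list NRARP fell 2.13-fold and NOTCH3 1.30-fold, while NOTCH2 rose 1.20-fold and HES1 1.47-fold.

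Mitosis genes were slightly higher, with 13 of 25 up, 3 down and 9 not passing, at a median log2 change of 0.17 (camera adjusted p = 0.0132; adjusted p = 0.388 with an estimated correlation). CDC20 rose 1.59-fold, CCNB1 1.38-fold, KIF23 1.37-fold and PLK1 1.35-fold. DNA replication genes did not pass as a list (6 higher, 10 lower, 10 not passing of 26; camera adjusted p = 0.518). MCM7, a helicase subunit, fell 1.42-fold, CDT1 1.37-fold and E2F1 1.35-fold, and RRM2 rose 1.20-fold. Replication-dependent histone genes were lower in 10 of 13, higher in 1 and not passing in 2, with a median log2 change of -1.01. The list was lower by camera (adjusted p = 3.54e-04), and adjusted p = 0.147 with an estimated correlation. Their transcripts mostly, but not always, lack poly(A) tails, so their counts may also reflect how RNA was selected. H2BC21 fell 2.998-fold, H1-2 2.43-fold, H2BC4 3.82-fold and H2BC5 1.59-fold, although histone genes are near-copies of one another. Targets of p53 went both ways (6 higher, 8 lower, 3 not passing of 17; camera adjusted p = 0.601), with GDF15 up 1.86-fold, TP53I3 up 2.04-fold, the cyclin-dependent kinase inhibitor CDKN1A down 1.54-fold and TNFRSF10B down 1.40-fold.

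Mesenchymal transition genes (8 higher, 4 lower, 3 not passing of 15; camera adjusted p = 0.422; 8 higher and 5 lower adjusted over the list alone) and epithelial adhesion genes (3 higher, 5 lower, 3 not passing of 11; camera adjusted p = 0.882) did not pass as lists. The transcription factor gene SNAI2 rose from 5.62 ± 1.37 to 31.03 ± 0.756 CPM and TGFBI 2.52-fold, whereas the integrin gene ITGA5 fell 1.84-fold and LOX 2.06-fold. CLDN1 rose 1.62-fold and JUP 1.29-fold, KRT18 fell 1.21-fold, and DSP fell 1.15-fold, a call that limma on FPKM rescaled to TPM did not make (adjusted p = 0.0990).

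Among markers of RNA handling, the 13 mitochondrially encoded genes were lower in 10, higher in 1 and not passing in 2, with a median log2 change of -0.50 (camera adjusted p = 2.47e-05; adjusted p = 0.494 with an estimated correlation), a call lost under quantile normalisation (0.313). All genes of the mitochondrial chromosome, not only these 13, made up 8.33%, 7.84% and 8.24% of counts in the control libraries. In the knockdown libraries their share was 6.95%, 6.30% and 6.14%. MT-CO1 was at 18142 ± 393 and 12578 ± 440 CPM, a change whose direction turned under quantile normalisation. That normalisation gives every library the same set of values, so it cannot test a fall shared by the most abundant genes. MT-CO1 had the most counts in every library. MT-CO2, lost under the same setting (0.0636), fell 1.72-fold, MT-ND5 1.505-fold and MT-ND6 1.57-fold in edgeR. Nuclear genes of oxidative phosphorylation did not pass as a list (9 higher, 5 lower, 12 not passing of 26; 9 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.473), but did in the higher direction with limma on FPKM without a filter (0.0135). UQCRC2 fell 1.28-fold, while COX5A and SDHD rose 1.22-fold and NDUFB10 1.28-fold. Cytosolic ribosomal protein genes were lower in 14 of 24, higher in 1 and not passing in 9 (median log2 change -0.14; camera adjusted p = 0.00201; adjusted p = 0.557 with an estimated correlation), a call lost under TPM scaling (0.205) and quantile normalisation (0.183). Adjusted over the list alone, 15 were lower. RPL4 fell 1.23-fold, RPL5 1.20-fold and RPL7A, lost under TPM scaling (0.0558), 1.18-fold. Heat shock and immediate stress genes did not pass as a list (7 higher, 5 lower, 2 not passing of 14; camera adjusted p = 0.896; mean -0.02, test higher), with HSPA8 up 1.40-fold, HMOX1 up 2.22-fold, JUN down 1.55-fold and JUNB down 1.51-fold.

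In total 14 of the 28 lists tested passed camera with the preset correlation, 4 higher and 10 lower in the knockdown. With an estimated correlation camera passed 0 lists, while 9 had an unadjusted p under 0.05. That form also has fewer degrees of freedom, so a lost call is not always due to correlated genes. The YAP/TAZ list had an estimated correlation of -0.0217, under the preset 0.01, yet its unadjusted camera p went from 2.58e-05 to 0.00981. For cytosolic ribosomal proteins the estimated correlation was 0.421. Fry, which asks only whether a list's own genes move one way, passed 22. Beyond those 14, fry passed the hepatocyte, Wnt, Notch and p53 lists in the lower direction and the lysosome, autophagy, unfolded protein response and bile duct lists in the higher direction. In the 21 lists for which no other count is given, the counts adjusted over the list alone were the same. The balance of calls depended on the scaling: 50.1% of the changed genes were higher with edgeR, 60.7% with limma on the deposited FPKM and 69.5% with limma after rescaling to TPM. The median log2 change of all genes tested was 0.01 with edgeR, 0.07 on FPKM and 0.14 after rescaling to TPM. A change given here from edgeR is relative to the first of these.

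Annotation terms carried by the deposited table were tested in the same way. Of 2273 terms, 10 passed camera in the higher and 11 in the lower direction; with an estimated correlation 0 passed (lowest adjusted p = 0.865), while 98 had an unadjusted p under 0.05. Proteasome genes were higher in 35 of 48 and lower in 2 (camera adjusted p = 6.57e-05), with PSME3 up 1.42-fold, PSMB2 1.39-fold and PSMC2 1.37-fold. Autolysosome genes were higher in 13 of 20 and lower in 2 (camera adjusted p = 0.00728). They included the ferritin chain genes FTH1, from 2873 ± 41.9 to 6316 ± 101 CPM, and FTL, from 606 ± 29.1 to 1234 ± 21.8 CPM; FTH1 has many processed pseudogenes. Prostaglandin metabolism (10 of 15 higher, 1 lower; camera adjusted p = 0.00390) was represented by AKR1C2, AKR1C3, up 2.91-fold, and PTGES, up 1.88-fold. Glutathione peroxidase activity (11 of 15 higher, 1 lower; camera adjusted p = 0.0471) included GSTP1, up 1.64-fold, and GPX8, up 1.83-fold. The proton-pumping ATPase of lysosomes and other organelles was higher in 15 of 21 and lower in 2 (camera adjusted p = 0.0471), with ATP6V0D1 up 1.80-fold. Spliceosomal genes were higher in 54 of 121 and lower in 15 (camera adjusted p = 0.0351), with RBM3 up 1.503-fold and RBMXL1, a retrocopy, down 1.73-fold.

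Among the terms that were lower, cholesterol biosynthesis led (26 of 34 lower, 1 higher; camera adjusted p = 9.17e-08), with MSMO1 down 3.01-fold. Integrin complex genes were lower in 11 of 18 and higher in 1 (camera adjusted p = 0.00390): ITGA2 fell from 1041 ± 31.96 to 157 ± 3.60 CPM, ITGB4 3.16-fold and ITGB8 3.86-fold. A set annotated to autoimmune thyroid disease was lower in 17 of 25 and higher in 2 (camera adjusted p = 0.00390). Its leading members were CGA, the alpha subunit shared by glycoprotein hormones, from 258 ± 9.57 to 22.99 ± 1.14 CPM, and HLA-B, down 2.58-fold. The response to hypoxia (58 of 110 lower, 25 higher; camera adjusted p = 0.00901) and glycolysis (18 of 38 lower, 6 higher; camera adjusted p = 0.0471) included ENO2, down 7.21-fold, and ALDOC, down 6.29-fold. Triglyceride synthesis was lower in 11 of 16 and higher in 2 (camera adjusted p = 0.00901), with LPIN1 down 4.25-fold and ACSL1 4.67-fold. Serine endopeptidase inhibitors were lower in 30 of 46 and higher in 12 (camera adjusted p = 0.0471), SERPINE2 from 1281 ± 19.7 to 282 ± 3.29 CPM. A set annotated to amphetamine response was lower in 10 of 16 and higher in 1 (camera adjusted p = 0.0439), with RGS2 down 3.67-fold and NR4A1 2.56-fold. The cytosolic ribosome term was lower in 63 of 148 and higher in 9 (camera adjusted p = 0.0426); its leading members were the pseudogene RPL13AP20, down 4.29-fold, RPS25, down 1.28-fold, and the co-activator gene PPARGC1A, up 2.64-fold.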

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

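All alternatives were planned except the fit with GC and length trends removed, which was chosen after the result was seen. The log2 change of LAPTM4B stayed lower and past the threshold under every alternative run, between -0.56 and -0.39. With edgeR or DESeq2 the counts of higher, lower and 2-fold changed genes stayed within 1.5 times, leave-one-out fits included; the GC and length correction gave 5184 higher, 3936 lower and 1768 changed at least 2-fold. No pairing by replicate number was seen. Deviations of same-numbered libraries had correlations of 0.023, -0.050 and -0.044 across genes, and those of different-numbered libraries -0.017 to 0.061. Such values cannot exclude a pairing, of which the labels say nothing. With the replicate block edgeR called 4441 genes higher, 4408 lower and 1821 changed at least 2-fold.

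Limma on FPKM called fewer genes lower: 2915, or 2925 and 2900 with pseudocounts of 1 and 0.01, 1829 with a mean of at least 5, where fewer genes were tested, 2330 after rescaling to TPM, 2823 without a trend and 2905 with robust estimation. It also called fewer genes changed at least 2-fold: 909, or 548 and 954 with pseudocounts of 1 and 0.01, where the higher one shrinks low genes, 337 with a mean of at least 5, 937 for TPM and for median-of-ratios factors, 924 for trimmed-mean factors, 909 for quantile normalisation, 887 without a trend, 901 with robust estimation and 928 with array weights. Without the FPKM filter limma called 1691 genes changed at least 2-fold and 3142 lower, over 34454 genes tested. The edgeR fit without a count filter called 2345 and 4636 over 34501 genes, so both gaps remained between the unfiltered fits. Scaling also moved the lower calls of limma: 3397 with median-of-ratios factors, 3101 with trimmed-mean factors and 3169 with quantile normalisation. What else lowers the counts was not tested. Of the gene lists, 14 passed in the main analysis, 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 22 with fry.

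Directions turned for 2 of the named genes. MT-CO1 was at 0.0747 under quantile normalisation, which by its method removes a fall shared by the most abundant genes. KLF4, which never passed, was at 0.04 in limma on FPKM, with no filter, a mean of at least 5, no trend or robust estimation (0.04385 each), at 0.042235 and 0.044018 with pseudocounts of 1 and 0.01, at 0.115 for TPM, 0.0043475 with trimmed-mean factors and 0.018358 with array weights; leave-one-out values ran from -0.056 to 0.023. Lists that did not pass turned direction at these adjusted p: Hippo components 0.906 (limma, no filter); hepatocyte genes 0.948 (limma on FPKM, no trend, robust, array weights), 0.938 and 0.946 (pseudocounts 1 and 0.01), 0.921 (TPM), 0.884 (median-of-ratios), 0.925 (trimmed-mean) and 0.933 (quantile); DNA replication 0.834 (limma, no filter) and 0.877 (TPM); mesenchymal transition 0.979 (mean of at least 5); epithelial adhesion 0.802 (edgeR, no filter), 0.829 (TPM), 0.795 without control replicate 3 and 0.988 without knockdown replicate 2; heat shock 0.967 (edgeR, no filter), 0.980 without control replicate 1 and 0.849 without control replicate 2. For KLF4 and these lists the cause was not tested.

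Among the other comparisons of named genes, outside the leave-one-out fits, 2674 kept direction and side of the threshold and 5 lost a call; of those leaving out a library 1037 kept both, 4 lost a call and 1 gained one. For the lists 455 and 163 kept both, 17 lost a call (14 of them with an estimated correlation) and 12 gained one, with 1 more gained in the leave-one-out fits. At total counts of 15204269 to 19987318, genes at a few counts per library, PROM1 among them, could not be tested.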

Other observations

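The gene lists of the next 2 paragraphs were composed after the values of their genes had been seen, so they are described without a list p-value. The tests of depth, cell identity, scaling, culture and cell density were also chosen after the result was seen; only the tests of other splits of the libraries and of GC content and length had their outcome criteria written before their result.

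Targets of the oxidative stress factor NRF2 were higher in the knockdown: 20 of 22 rose, 1 fell and 1 did not pass, with a median log2 change of 1.06. GCLM, a subunit of the glutathione synthesis enzyme, rose from 44.2 ± 2.95 to 152 ± 5.88 CPM, the cystine transporter gene SLC7A11 from 155 ± 27.6 to 505 ± 4.75 CPM, TXNRD1, thioredoxin reductase, from 487 ± 15.2 to 1029 ± 18.99 CPM and NQO1 from 131 ± 4.43 to 242 ± 5.14 CPM. The member that fell was PGD, from 253 ± 9.30 to 211 ± 5.61 CPM. Several of these genes, such as SLC7A11, ABCC2 and FTH1, also stand in lists or terms described above, so this is not a separate line of evidence. Targets of the oxysterol receptor LXR were lower, 6 of 8 tested with none higher (median log2 change -1.72). The cholesterol exporter ABCG1 fell from 55.1 ± 3.46 to 5.50 ± 1.09 CPM beside ABCA1, and MYLIP, a ubiquitin ligase gene, from 16.2 ± 1.74 to 3.04 ± 0.486 CPM. LXR targets and the sterol synthesis genes thus fell in the same libraries.

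Of 25 targets of the hypoxia-inducible factors 22 fell, none rose and 3 did not pass (median log2 change -1.22). Such targets also stand in the glycolysis and hypoxia list above, so this is not a separate line of evidence. PDK1 fell from 75.9 ± 6.43 to 22.7 ± 2.40 CPM, MXI1 from 141 ± 5.41 to 28.9 ± 2.40 CPM and the lipid droplet protein gene HILPDA from 54.4 ± 2.22 to 12.4 ± 0.730 CPM. Among 5 tested EGFR ligands 2 fell, 1 rose and 2 did not pass. AREG and EREG fell, EGF went from 2.09 ± 0.121 to 4.11 ± 0.478 CPM, and TGFA was at 18.98 ± 1.95 and 18.3 ± 1.49 CPM. Of 11 trophoblast genes tested 8 rose, 2 fell and 1 did not pass. The pregnancy-specific glycoprotein gene PSG4 rose from 0.421 ± 0.0992 to 10.2 ± 1.37 CPM, with reads that its family members could share. ALPP and CGA, both placental products, moved in opposite directions.

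Many hepatocyte genes were at or under the counting limit in libraries whose labels give HepG2, a line known for secreting plasma proteins. Of 36 such genes 41.7% had at most 3 counts in every library, against 1.97% of the 508 genes of the other lists that mark no cell type. Fisher's exact test gave p = 1.82e-13, but it treats the genes as independent. Of the 508 genes 84.3% exceeded 10 CPM in the control cells, so most would pass 3 counts at lower depth too. The contrast is thus a weak test of shallow sequencing or a general loss of counts. It shows that the scarcity was not shared by most genes of the other lists. PROM1, which encodes CD133, was at 1 to 3 counts in the control libraries, which goes against the labelled selection at the transcript level. Only 3 of the 36 exceeded 10 CPM in the control cells, while genes named here after their values were seen were abundant in both groups, such as FOLR1 at 2738 ± 67.1 and 2028 ± 43.97 CPM, MUC13 at 1274 ± 40.4 and 861 ± 8.87 CPM and KRT8 at 674 ± 37.5 and 777 ± 10.2 CPM. Cells of another line and hepatoma cells that lost the hepatocyte programme cannot be told apart here. Both predict scarce hepatocyte transcripts, and no reference profile was used to say which cells would hold the abundant genes.

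Of the tested genes 9143, or 55.9%, changed while LAPTM4B fell by 30.6%. With edgeR 1 of the 10 splits of the 6 libraries, the real one, gave that many, and the highest of the others gave 0 genes. At an unadjusted edgeR p under 0.05 the others gave at most 235. Limma on FPKM gave 7411 for the real split and at most 0 for the others, with at most 204 unadjusted. The other splits put libraries of both groups on each side, so the difference between groups entered their spread and held down their calls. Their low counts thus decide nothing, and 10 splits are too few for a share under 0.05. The choice among the scalings tried is argued against as the whole source. With edgeR and median-of-ratios factors 55.6% of the same 16354 genes were called. The lowest share among the scalings compared was 52.4%, from limma on FPKM with trimmed-mean factors. That share changes the test and the genes as well, with 13018 tested. DESeq2, another test with its own size factors, called 49.8% of the 16354 genes. A trend on GC content or gene length is argued against too, since 93.1% of the calls were made in the same direction once it was removed. A culture or handling difference between the control set and the knockdown set stays open. The libraries of a group varied by 4.16% (coefficient of variation), and the labels name no culture, day or batch. Set and group therefore cannot be told apart from an effect of the knockdown. The knockdown reagent and its sequence are not given in the labels either, so its effects on genes other than LAPTM4B could not be examined. Markers of RNA handling also shifted with the group. All genes of the mitochondrial chromosome held 7.84% to 8.33% of control counts and 6.14% to 6.95% of knockdown counts. Histone genes had a median log2 change of -1.01. Handling or a change in the cells could both give these shifts.

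Glycolysis and hypoxia genes, HIF targets among them, and cholesterol synthesis genes were lower while YAP/TAZ targets were higher by camera with the preset correlation. None of the 3 lists passed camera with an estimated correlation (adjusted p = 0.115, 0.0973 and 0.0588). The correlations estimated were 0.193, 0.228 and -0.0217, so for the YAP/TAZ list correlated members do not explain the loss. A GC or length trend is argued against for HIF targets, cholesterol synthesis and YAP/TAZ targets. After its removal their medians kept their sign and at least 0.925 of their size. The HIF targets here are the list composed after the values were seen. The median of the fixed glycolysis and hypoxia list was not checked in this way. A candidate explanation is denser or less oxygenated control cultures: low oxygen raises HIF targets and high density restrains YAP, while no test here related the cholesterol synthesis genes to either. DNA replication genes, which would be higher in a sparser knockdown culture, had a median log2 change of -0.023 with members going both ways, while mitosis genes had 0.17, so this stays open. The labels give neither density nor oxygen, so it cannot be told apart from an effect of the knockdown.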
